A study of Mus musculus with 4 samples.

How the data were processed

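Colon tumours from 4 AOM/DSS mice were measured by CAGE, 2 from mice given an anti-MAdCAM-1 antibody and 2 from mice given control IgG. Per the labels, RNA was purified on RNeasy columns and used at an RNA integrity number above 7.0. Random-primed cDNA was selected by cap-trapping and read as single ends of 75 nt on a NextSeq 500. The authors mapped tags to GRCm39 with BWA 0.7.17 and the unmapped reads with HISAT2 2.0.5, and clustered them with RECLU, a pipeline around a modified Paraclu. They discarded clusters under 0.1 CPM, those with an irreproducible discovery rate of 0.1 or more and those over 200 bp, and kept regions that overlapped by 90% between replicates (bedtools 2.12.0). They named edgeR 3.22.5 for expression. How clusters were summed to genes is not stated in the sources used. The deposited table holds raw tag counts per gene, which were checked to be whole numbers with totals that differ between libraries.

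The 4 libraries held 16891234, 15727936, 14850923 and 15895228 tags (IgG 1, IgG 2, MAdCAM1 1, MAdCAM1 2), so that 1 tag equals 0.0569, 0.0618, 0.0700 and 0.0648 CPM. Gene coordinates came from GENCODE M39 on the same build, which matched 14289 of the tested genes (99.7%). In all, 885 genes with at least 20 tags share their values with another gene in all 4 libraries. Among list members these include Cd3e, Iglc2, Spp1, Itgam, Ltb, Mef2b, Col1a2, Col3a1 and several mitochondrial genes.

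Genes were filtered with filterByExpr by group (14331 of 14979 kept) and scaled by TMM (factors 1.04, 1.03, 0.962 and 0.972). The comparison was MAdCAM1 minus IgG in edgeR 4.0.16 under R 4.3.3, by the robust quasi-likelihood F test with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The common biological coefficient of variation was 0.322 and the median prior degrees of freedom 2.34. Pearson correlations of log2 CPM across genes were 0.942 within IgG and 0.944 within MAdCAM1, and 0.914 to 0.949 between the groups. Genes are not independent replicates. The first 3 principal components held 46.4%, 28.4% and 25.2% of the variance.

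There were 39 gene lists, written before the data were examined, covering immune cell types, inflammatory signalling, epithelial lineages, stroma and tumour pathways. The 36 lists with at least 3 tested members were tested by camera (limma 3.58.1, two-sided, preset correlation 0.01, prior count 2), with Benjamini-Hochberg adjustment over the lists. Named genes followed rules also set before the data were examined. These were the antibody target and its ligand, up to 4 members of each list with the smallest p, and 5 sex-linked genes. Added to them were the 10 genes per direction with the smallest p among named genes of mean CPM at least 1. Only genes whose values did not overlap between the groups could enter these 10. Of the 10 lower genes, 2 are not used here. Other named list members, such as Slc26a3, Aqp8, Car4, Muc2, Chga, Atoh1, Lcn2, Retnlb, Ang4, Cldn4, Axin2, Lgr5, Smoc2, Vegfa, Mki67, Cd3g, Lyz2, Il1b, Socs1, Isg15, H2-K1, Cd74 and Cnn1, were chosen after their values were seen.

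Alternatives were RLE, upper quartile and library size scaling, no filter, a CPM of at least 1 in 2 libraries, leaving out each library, a replicate block, removal of immunoglobulin and T cell receptor segments, DESeq2 1.42.0, limma-voom, edgeR's exact test, camera with an estimated correlation and fry. Counting identical genes once and using the smooth muscle level as a covariate were added after the data were seen. The replicate numbers belong to different mice, so the main comparison has no block. The 4 gene tests were tested on simulated data with 50 genes planted per fold change among 14331. The quasi-likelihood test recovered 0, 27, 41 and 46 of them at 2, 4, 8 and 16-fold with 22 false calls, and the exact test 3, 37, 48 and 50 with 59 false calls. DESeq2 recovered 4, 39, 45 and 47 with 80 false calls, and limma-voom 0, 26, 40 and 47 with 17. Each gene was drawn independently, with a spread fitted to the real libraries, so the recovered numbers need not hold for the real data. There Spink1, at 7.25-fold, had an adjusted p of 0.484 by the quasi-likelihood test. The list tests were tested on simulated data of 14216 genes, drawn independently of each other, with a list planted at 2-fold. Its adjusted p was 3.5e-12 by camera with the preset correlation, 0.547 with an estimated correlation and 0.00894 by fry, and of 36 unchanged lists they called 1, 0 and 1. No column of the table was left out.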

Results

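Colon tumours were profiled by CAGE (cap analysis of gene expression), which sequences short tags from the capped 5′ ends of RNA and counts them per gene. The tumours came from mice given azoxymethane and dextran sulfate sodium (AOM/DSS), a carcinogen followed by a chemical that inflames the colon, so that tumours arise in chronic colitis. One group received an antibody against MAdCAM-1, the adhesion molecule on gut venules to which lymphocytes carrying the α4β7 integrin bind, and the other received a control IgG antibody. Each group held 2 mice with 1 library per mouse, named here IgG 1, IgG 2, MAdCAM1 1 and MAdCAM1 2. The libraries held 16891234, 15727936, 14850923 and 15895228 tags in that order, over 14979 genes. Of these, 14331 genes had enough tags to be tested. Levels are given as CPM (tag counts scaled to library size, with TMM factors), and log2 fold changes are MAdCAM1 over IgG, so that a positive value means a higher level in tumours of antibody-treated mice. The p-values of single genes set the difference between the groups against the spread between mice within them. That spread is estimated partly from other genes. The p-values of camera set the genes of a list against the other genes.

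The comparison of the 2 antibody groups asks whether blocking MAdCAM-1 alters immune cell content and inflammatory signals in these tumours. Most listed genes of differentiated colon epithelium were higher in both MAdCAM1 libraries than in both IgG libraries. They covered absorptive colonocytes, mucus-secreting goblet cells and hormone-secreting enteroendocrine cells, together with epithelial defence genes such as Dmbt1 and Duox2. Target genes of Wnt signalling, the pathway that drives most colon tumours, were lower as a list. The calls of the epithelial, defence and Wnt lists were lost with an estimated correlation between genes (adjusted p = 0.971 with an estimated correlation), and that of Wnt targets also without MAdCAM1 2 (median log2 fold change −0.18, adjusted p = 0.180). Lists of T cells, macrophages and inflammatory cytokines were not called, and B and plasma cell genes were far higher in MAdCAM1 2 alone. These uncalled lists were less complete, with 9 of 20 T cell, 14 of 20 macrophage and 13 of 31 cytokine members tested. Of the goblet cell list 15 of 15 members were tested, and of the colonocyte list 19 of 22. No single gene passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, so these statements rest on gene lists and on the values of each library. The number of list calls does not set the real groups apart. Pairings of the libraries that mix the treatments gave 23 and 12 calls, against 7 for the real groups. Colonocytes, goblet cells and general epithelium were also called in the pairing with 23 calls, and Wnt targets in that with 12.

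The antibody target and its ligand were low. Madcam1 (chromosome 10, 79500209 to 79504371, GRCm39) stood at 4.33 and 4.64 CPM in the IgG libraries and at 1.61 and 9.91 CPM in the MAdCAM1 libraries, a log2 fold change of 0.36 (SE 0.89, n = 2 per group; edgeR adjusted p = 0.960). Itgb7 (chromosome 15, 102124429 to 102140379), the β7 chain of the integrin that binds MAdCAM-1, stood at 4.10, 4.08, 2.45 and 11.5 CPM in the order IgG 1, IgG 2, MAdCAM1 1, MAdCAM1 2 (log2 fold change 0.77, SE 0.79; adjusted p = 0.880). Itga4, its α4 chain, had 4, 6, 2 and 20 tags in the same order and was too low to be tested. For all 3 genes the highest value was in MAdCAM1 2 and the lowest in MAdCAM1 1. Xist, transcribed from the inactive X chromosome of females, had 3204, 4002, 4987 and 2974 tags in that order, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty are not listed among the genes analysed here.

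Across all genes, 0 of 14331 were called in either direction by the edgeR quasi-likelihood test, with a smallest adjusted p of 0.484. At an unadjusted p under 0.05 that test had 730 genes higher and 261 lower. Scaling by library size alone, which shifted the median log2 fold change of all genes to −0.10, gave 527 higher and 565 lower at that level. edgeR's exact test called 148 genes higher and 9 lower, DESeq2 called 219 higher and 20 lower, and limma-voom called 0. The exact test and DESeq2 shared 138 calls, all in the same direction. Values of the groups did not overlap for 2825 genes that were higher (19.7%) and 2674 that were lower (18.7%), where chance gives 16.7% each. Scaled by library size alone, the shares were 13.6% higher and 28.6% lower. Parting the libraries into pairs that mix the treatments gave 21.4% and 17.7% on the sides of the crossed pairing. These shares therefore do not set the real groups apart. With TMM and a fold change of at least 2, genes without overlap between the real groups numbered 581 higher and 182 lower.

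The genes with the smallest p among those higher in the MAdCAM1 group, none of which passed the main test, included genes for a protease inhibitor, metabolic enzymes and a hormone. Spink1 (chromosome 18, 43861139 to 43870622), a secreted inhibitor of trypsin, stood at 48.8 and 42.2 CPM in the IgG libraries and at 332 and 328 CPM in the MAdCAM1 libraries. Its log2 fold change of 2.86 (SE 0.16) had the smallest quasi-likelihood adjusted p of 0.484, with 5.3e-16 by the exact test and 6.3e-43 by DESeq2. The others were the metabolic enzymes Akr1c14 (log2 fold change 3.49), Ces2e (2.76) and Sult1c2 (3.55), the glycosyltransferase Mgat4c (2.01), the brush border cadherin Cdhr2 (1.51), the serine protease Prss30 (2.30), Ly6m (1.40), the tight junction gene Cldn8 (2.17) and the hormone gene Ppy (5.01). Akr1c14, for example, had 2.79 and 1.92 CPM in IgG and 26.5 and 26.5 CPM in MAdCAM1. Ppy rested on 5 and 2 tags in the IgG libraries against 91 and 114. All 10 were called by both the exact test and DESeq2. Both tools used the same counts, so their calls are not independent of each other. In simulated data they made 59 and 80 false calls in that order. The exact test also called 116 genes in a pairing of the libraries that mixed the treatments, against 157 for the real groups. Their values did not overlap between the groups, which the rule that chose them required.

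The lower genes with the smallest p also failed the main test, and 8 of them are given here, at adjusted p between 0.640 and 0.665. The amino acid transporter Slc38a4 (chromosome 15, 96892693 to 96958593) stood at 10.9 and 10.4 CPM in IgG and 2.10 and 1.75 CPM in MAdCAM1, a log2 fold change of −2.46 (SE 0.31). Slc7a11, which imports cystine for glutathione synthesis, had 80.5 and 63.2 CPM against 28.8 and 22.3 CPM (log2 fold change −1.49, SE 0.22). The laminin receptor Bcam had a log2 fold change of −1.36, the transcriptional repressor Zbtb7c −1.43, Pex5l −1.65, Arl4c −0.99 and the deglycosylating enzyme Engase −0.75. Camp, the cathelicidin of neutrophil granules, had 37 and 30 tags in IgG and 1 and 3 tags in MAdCAM1. DESeq2 called 7 of these 8 genes, all but Camp, and the exact test called 6, all but Arl4c and Engase. The limits of these 2 tools given for the higher genes hold here too.

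Absorptive colonocyte genes were higher as a list. Of 19 tested members, 15 were higher in both MAdCAM1 libraries than in both IgG libraries and 0 were lower in both, with a median log2 fold change of 1.77. Krt20, a keratin of mature surface cells, stood at 135 and 96.7 CPM in IgG and 294 and 366 CPM in MAdCAM1. Slc26a3, the chloride and bicarbonate exchanger of surface colonocytes, stood at 1.99 and 0.495 against 22.8 and 10.9 CPM, and the carbonic anhydrase Car4 at 3.36 and 0.742 against 99.8 and 14.9 CPM. The water channel Aqp8 stood at 0.455 and 0.0618 CPM in IgG and at 11.3 and 3.37 CPM in MAdCAM1. The list passed camera, which sets a list against all other genes at a preset correlation of 0.01, with an adjusted p of 7.5e-11. With the correlation of 0.494 estimated from the data the call was lost (adjusted p = 0.971 with an estimated correlation). Over all genes 0 members were called by edgeR's quasi-likelihood test, 6 by the exact test and 8 by DESeq2, and 6 were called by the quasi-likelihood test when adjusted over the list alone. The colonocyte median was 2.48 without IgG 1 and 1.29 without IgG 2.

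Goblet cell genes were higher in the same way, with 11 of 15 tested members higher in both MAdCAM1 libraries, 0 lower in both and a median log2 fold change of 1.88. Muc2, the main mucin of the colon, stood at 364 and 125 CPM in IgG and 1876 and 1136 CPM in MAdCAM1. The trefoil peptide Tff3 went with it at 303 and 170 against 1252 and 1192 CPM, and the mucus lectin Zg16 at 28.5 and 6.74 against 1197 and 347 CPM. Atoh1, the transcription factor that specifies secretory cells, overlapped between the groups at 33.7, 5.999, 47.7 and 28.0 CPM. Enteroendocrine genes had 6 of 9 members higher in both, 0 lower in both and a median of 2.35. Pyy, a hormone of colonic L cells, stood at 14.9 and 4.70 against 95.6 and 105 CPM, and Chga, a component of secretory granules, at 3.81 and 0.495 against 9.87 and 12.2 CPM. Camera adjusted p-values were 2.4e-09 for goblet cells and 9.6e-06 for enteroendocrine cells, and both had adjusted p = 0.971 with an estimated correlation. The quasi-likelihood test called 0 members of either list over all genes, and 5 goblet and 1 enteroendocrine genes when adjusted over the list alone. Over all genes the exact test called 4 goblet and 2 enteroendocrine genes, and DESeq2 5 and 2. The goblet median was 2.83 without IgG 1 and 1.17 without IgG 2, and the enteroendocrine median was 4.46 without IgG 1 and 1.96 without IgG 2.

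General epithelial genes were also higher. Of 14 members, 12 were higher in both MAdCAM1 libraries and 1 was lower in both, with a median log2 fold change of 0.73. Epcam stood at 1945 and 2049 CPM in IgG and 3185 and 2811 CPM in MAdCAM1, and Phgr1 at 200.3 and 140 against 615 and 519 CPM. Cldn4 was the member lower in both, at 536 and 569 against 449 and 285 CPM. The list of epithelial antimicrobial and oxidative defence had 11 of 16 members higher in both, 1 lower in both and a median of 1.08. Dmbt1, a secreted mucosal scavenger protein, stood at 995 and 803 against 2604 and 3131 CPM. Duox2, an oxidase that makes hydrogen peroxide at the epithelial surface, stood at 87.7 and 70.5 against 178 and 149 CPM, and Pigr, which carries IgA across epithelium, at 303 and 197 against 657 and 588 CPM. Lcn2, an inflammation marker in the same list, overlapped at 260.2, 709, 571 and 199 CPM. Camera adjusted p-values were 2.7e-06 for general epithelium and 8.6e-07 for the defence list, and both had adjusted p = 0.971 with an estimated correlation. The quasi-likelihood test called 0 members over all genes, and 7 and 5 when adjusted over the list alone. Over all genes the exact test called 2 in each list, and DESeq2 4 epithelial and 7 defence genes. Retnlb and Ang4 stand in both the goblet and the defence list.

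**Figure D1:**
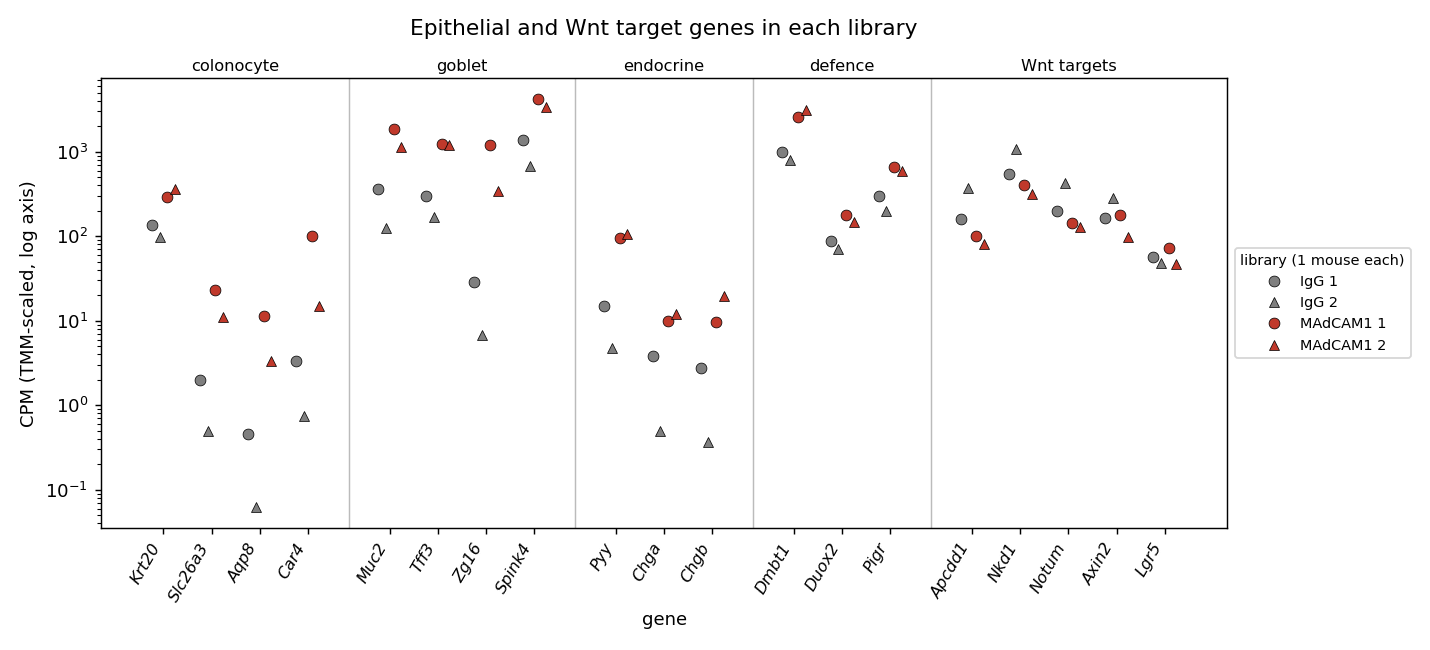
TMM-scaled CPM on a log axis for genes of 5 lists in each of the 4 libraries (grey IgG, red MAdCAM1; circle mouse 1, triangle mouse 2). Muc2 lies at 364 and 125 CPM in IgG and at 1876 and 1136 CPM in MAdCAM1, whereas Axin2 and Lgr5 overlap between the groups.

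Wnt/β-catenin targets formed the list that was lower. Of 24 tested members, 9 were lower in both MAdCAM1 libraries, 0 were higher in both, and the median log2 fold change was −0.58. The Wnt inhibitor gene Apcdd1 stood at 161 and 376 CPM in IgG and 101 and 80.7 CPM in MAdCAM1, and the feedback inhibitor Nkd1 at 544 and 1084 against 399 and 320.3 CPM. Notum, which inactivates Wnt ligands, stood at 198 and 426 against 143 and 128 CPM, and Prox1 at 190.0 and 248 against 144 and 98.0 CPM. The stem cell genes Lgr5 (56.7, 47.9, 72.7 and 47.1 CPM) and Smoc2 (97.9, 107, 103 and 99.6 CPM) overlapped, as did the pathway reporter Axin2 (163, 282, 177 and 98.2 CPM). The camera adjusted p was 9.4e-05, with adjusted p = 0.971 with an estimated correlation. The quasi-likelihood test called 0 members over all genes and 0 when adjusted over the list alone, the exact test called 0 over all genes, and DESeq2 called 1 (Apcdd1, adjusted p = 0.0326). The call was lost without MAdCAM1 2 (median −0.18, camera adjusted p = 0.180), and the median was −0.91 without IgG 1, −0.22 without IgG 2 and −1.01 without MAdCAM1 1.

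Hypoxia and angiogenic growth factor genes were the remaining called list, with 9 of 14 members higher in both MAdCAM1 libraries, 0 lower in both and a median log2 fold change of 0.45. Car9, a carbonic anhydrase induced by low oxygen, stood at 10.98 and 11.4 CPM in IgG and 25.6 and 32.9 CPM in MAdCAM1, and Ankrd37 at 10.2 and 7.67 against 18.8 and 19.2 CPM. Vegfa overlapped at 64.3, 78.0, 122 and 69.2 CPM. The camera adjusted p was 0.00026, with adjusted p = 0.971 with an estimated correlation, and the median was 0.29 without MAdCAM1 1. The quasi-likelihood test called 0 members over all genes and 1, Car9, when adjusted over the list alone, and the exact test and DESeq2 each called 1 over all genes. Cell cycle genes had a median of 0.13, with 8 of 23 members higher in both and 0 lower in both. Ccna2 stood at 56.9 and 53.5 against 78.1 and 75.6 CPM, whereas Mki67 overlapped at 97.8, 54.1, 81.5 and 77.5 CPM, and the list was not called (camera adjusted p = 0.142) except without MAdCAM1 2 (median 0.26).

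**Figure D2:**
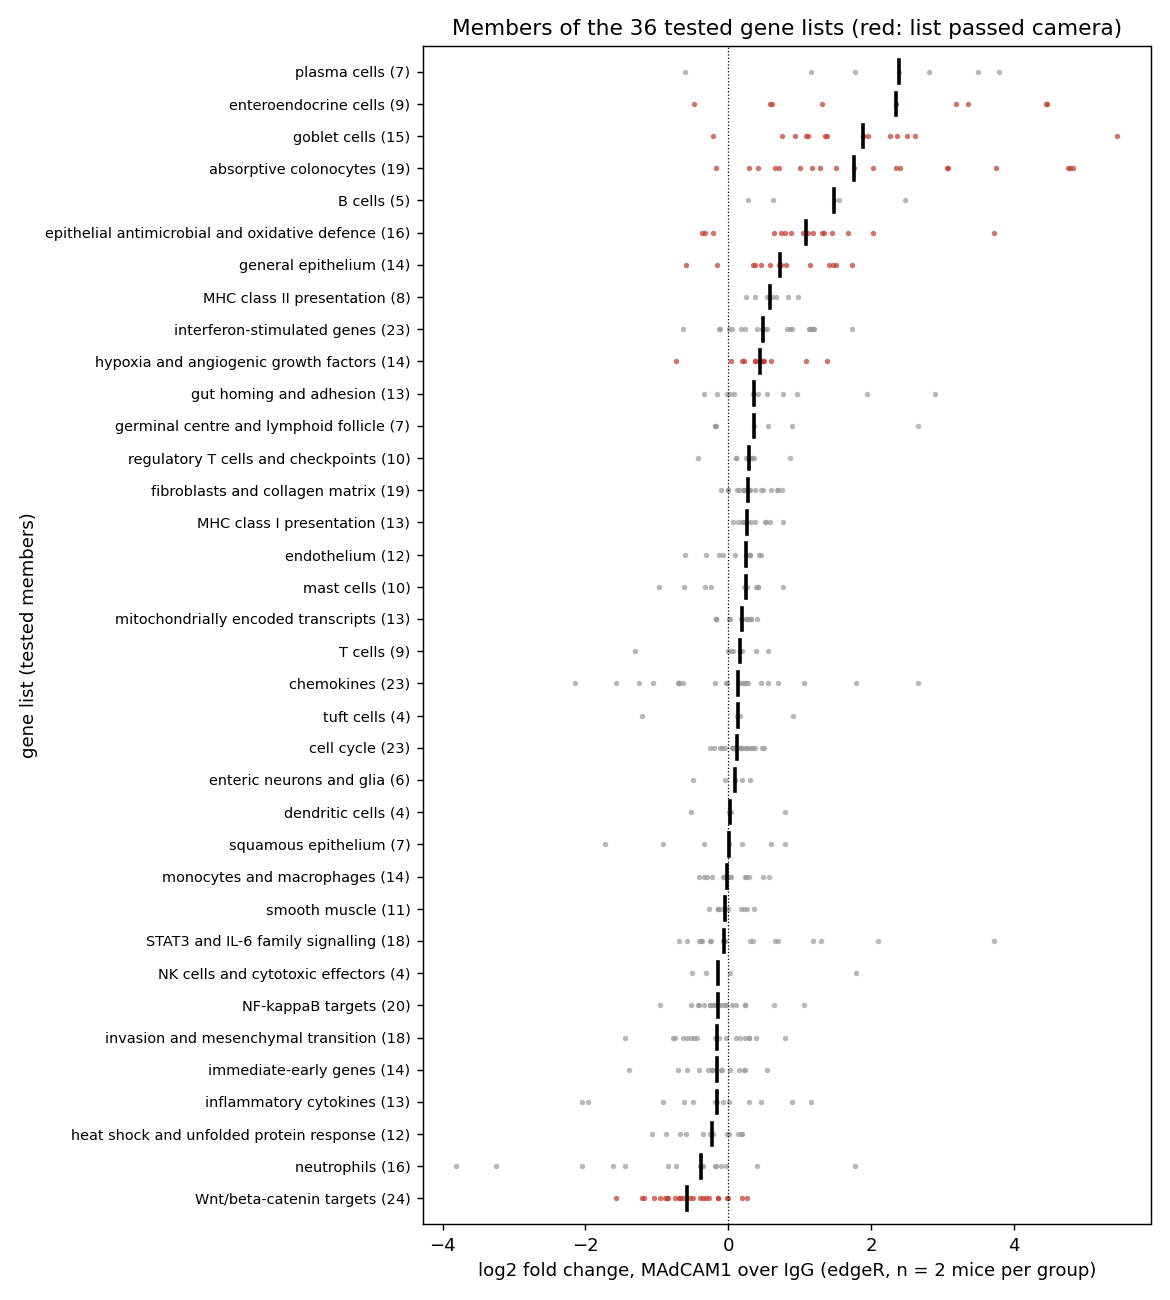
Each point is the log2 fold change (MAdCAM1 over IgG, n = 2 mice per group) of a member of 1 of the 36 tested gene lists, with the list median as a black bar and the number of tested members in brackets. Red marks the 7 lists that passed camera at the preset correlation, with medians from −0.58 for Wnt/β-catenin targets to 2.35 for enteroendocrine cells.

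Plasma cell and B cell genes were far higher in MAdCAM1 2 than elsewhere. Jchain, which joins IgA and IgM units, stood at 8.14, 35.4, 42.7 and 449.6 CPM in the order IgG 1, IgG 2, MAdCAM1 1, MAdCAM1 2, Mzb1 at 0.285, 0.433, 1.33 and 8.74 CPM, and the B cell receptor gene Cd79a at 8.76, 2.23, 1.12 and 60.3 CPM. Immunoglobulin and T cell receptor segments made up 0.0146%, 0.0452%, 0.0544% and 0.561% of tags in that order, and 103 of the 106 tested segments were highest in MAdCAM1 2. Plasma cells had a median log2 fold change of 2.39 with 4 of 7 members higher in both MAdCAM1 libraries (camera adjusted p = 0.142), and without MAdCAM1 2 the median was 0.21. B cells had a median of 1.49 with 0 of 5 members on one side (adjusted p = 0.929), and −2.29 without MAdCAM1 2. The germinal centre and lymphoid follicle list had a median of 0.36 over 7 members (adjusted p = 0.892). Its follicle chemokine Cxcl13 stood at 2.05, 2.29, 3.08 and 24.4 CPM. Camera called these 3 lists higher without MAdCAM1 1, at medians of 2.89 for plasma cells, 2.39 for B cells and 1.14 for the follicle list. Without MAdCAM1 2 it called B cells lower and the follicle list lower (−0.22).

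T cell genes did not separate the groups. Cd3g, a chain of the T cell receptor complex, stood at 7.80, 6.37, 3.78 and 12.4 CPM, and 0 of 9 T cell members were higher in both MAdCAM1 libraries. Zap70, a kinase of T cell signalling, was lower in both at 13.03 and 31.2 against 8.12 and 9.84 CPM. The median was 0.16 (camera adjusted p = 0.735). Regulatory T cells and checkpoints had a median of 0.29 (10 members, adjusted p = 0.588), with Foxp3 at 0.683, 1.42, 0.630 and 3.17 CPM. NK cells and cytotoxic effectors had a median of −0.14 (4 members, adjusted p = 0.643), with Gzmb at 5.24, 10.4, 5.04 and 7.51 CPM. The gut homing and adhesion list had a median of 0.36 with 3 of 13 members higher in both and 1 lower in both (adjusted p = 0.596). Among them, Ccl28, an epithelial chemokine that attracts IgA plasma cells, stood at 8.71 and 2.54 CPM in IgG and 43.2 and 40.9 CPM in MAdCAM1, and was called by the exact test (adjusted p = 0.00656) and by DESeq2 (adjusted p = 0.000534). Icam1 was lower in both at 65.8 and 76.3 against 60.1 and 52.6 CPM. Without MAdCAM1 2 camera called all 4 lists lower, at medians of −0.85 for T cells, −0.61 for regulatory T cells, −1.63 for NK cells and −0.59 for gut homing. Without MAdCAM1 1 it called regulatory T cells (0.67) and gut homing (1.14) higher.

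Myeloid lists were not called in the main setting. Monocytes and macrophages had a median log2 fold change of −0.02 over 14 members (camera adjusted p = 0.892), and differed widely within each group, as for Lyz2, a macrophage lysozyme, which stood at 96.6, 377, 95.9 and 384 CPM. Dendritic cells had a median of 0.03 over 4 members (adjusted p = 0.892), with Ccr7 at 2.22, 2.47, 0.840 and 7.32 CPM. Neutrophils had a median of −0.38, with 4 of 16 members lower in both and 1 higher in both (adjusted p = 0.0783). Camera called this list lower with no filter (−0.39) and with the replicate block (−0.28). Ngp, a granule protein of immature neutrophils, was lower with Camp, at 6.03 and 7.30 against 0.140 and 1.23 CPM, whereas the surface marker Ly6g was the member higher in both, at 55.9 and 36.0 against 126 and 188 CPM. Camp and Ly6g were the 2 neutrophil genes called by the quasi-likelihood test when adjusted over the list alone, and over all genes the exact test called both and DESeq2 called Ly6g. Mast cells had a median of 0.25 over 10 members (adjusted p = 0.892), with Tpsb2 at 12.8 and 15.9 against 10.1 and 8.55 CPM. Of the eosinophil list, only Alox15 was measured well enough, and it stood at 79.0 and 39.3 CPM in IgG and 17.4 and 16.6 CPM in MAdCAM1 (log2 fold change −1.80, SE 0.39, exact test adjusted p = 0.0145). It was the 1 gene of that list called when adjusted over the list alone, where with 1 tested member the adjustment leaves p unchanged. Without MAdCAM1 2 camera called monocytes (−1.30), dendritic cells (−1.11) and neutrophils (−0.74) lower, and without IgG 1 it called neutrophils lower (−0.87). Without MAdCAM1 1 it called monocytes (0.59) and dendritic cells (0.42) higher.

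Inflammatory cytokines had a median log2 fold change of −0.16, with 3 of 13 members lower in both MAdCAM1 libraries and 2 higher in both (camera adjusted p = 0.506). Tnf stood at 36.7 and 36.1 CPM in IgG and 29.5 and 22.3 CPM in MAdCAM1, Il17a at 3.41 and 4.64 against 1.75 and 0.194 CPM, and Csf3 at 5.81 and 2.29 against 0.560 and 1.49 CPM. Il18, a cytokine that epithelium makes, was higher in both at 41.7 and 51.3 against 126 and 81.0 CPM. Il1b overlapped at 11.3, 17.01, 15.1 and 10.2 CPM. Chemokines had a median of 0.14, with 4 of 23 members lower in both and 3 higher in both (adjusted p = 0.588). Cxcl5, a neutrophil attractant, stood at 183 and 185 against 117 and 111 CPM, Ccl20 at 38.3 and 20.4 against 12.7 and 12.0 CPM, and Cxcl10 at 62.4 and 46.6 against 19.7 and 32.7 CPM, while Ccl6 was higher at 244 and 171 against 385 and 485 CPM. NF-κB targets had a median of −0.15, with 6 of 20 members lower in both and 4 higher in both (adjusted p = 0.547), and Nfkb2 stood at 46.8 and 50.5 against 36.3 and 35.9 CPM. The STAT3 and IL-6 family list had a median of −0.06, with 4 of 18 members higher in both and 3 lower in both (adjusted p = 0.826). Its acute-phase genes Lrg1 (51.4 and 79.6 against 171 and 151 CPM) and Saa1 (49.4 and 93.9 against 427 and 184 CPM) were higher, while Saa3 (22.99, 277, 66.3 and 316 CPM) and Hp (18.0, 84.9, 24.9 and 138 CPM) overlapped. Socs1, a feedback inhibitor of cytokine signalling, was lower (45.8 and 51.8 against 37.7 and 38.0 CPM). Over all genes 0 members of these 4 lists were called by edgeR's quasi-likelihood test, and 0 when adjusted over the list alone. The exact test called 2 STAT3 list members, and DESeq2 called 2 of those, 1 cytokine and 2 chemokines. Without MAdCAM1 2 camera called the chemokines lower (median −0.67).

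Most antigen presentation and interferon genes were highest in MAdCAM1 2. Interferon-stimulated genes had a median log2 fold change of 0.49, with 1 of 23 members higher in both and 1 lower in both (camera adjusted p = 0.142), and Isg15 stood at 123, 44.3, 59.4 and 318 CPM in the order IgG 1, IgG 2, MAdCAM1 1, MAdCAM1 2. MHC class I presentation had a median of 0.27 with 0 of 13 members on one side (adjusted p = 0.277). H2-K1, a classical class I gene, stood at 3170.3, 898, 1676 and 3218 CPM. MHC class II presentation had a median of 0.59 with 0 of 8 members on one side (adjusted p = 0.588), and Cd74 stood at 1071, 683, 531 and 2033 CPM. Camera called all 3 lists higher without MAdCAM1 1, at medians of 1.07, 0.66 and 1.20 in the order given. Without MAdCAM1 2 it called interferon-stimulated genes (−0.40) and class II (−0.73) lower, and without IgG 1 it called interferon-stimulated genes (1.003) and class I (1.34) higher.

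Smooth muscle and stromal genes differed more between libraries of the same group than between the groups. Des, the intermediate filament of muscle, stood at 327 and 2.10 CPM in the IgG libraries and at 18.4 and 403 CPM in the MAdCAM1 libraries. Cnn1, a regulator of muscle contraction, stood at 281 and 3.53 against 19.4 and 301 CPM. The smooth muscle list had a median log2 fold change of −0.05 over 11 members (camera adjusted p = 0.892), and its median level was 259 and 14.7 CPM in IgG and 18.1 and 276 CPM in MAdCAM1. Fibroblasts and collagen matrix had a median of 0.27 over 19 members (adjusted p = 0.892), with Dcn, a matrix proteoglycan, at 105, 153, 58.4 and 355 CPM. Endothelium had a median of 0.25 over 12 members (adjusted p = 0.735), with Pecam1 at 8.59, 10.6, 4.97 and 18.7 CPM. No member of these 3 lists lay on one side of the other group. Without MAdCAM1 1 camera called all 3 lists higher (0.84, 0.96 and 0.91 in the order given) and without MAdCAM1 2 all 3 lower (−2.90, −1.05 and −1.17). Without IgG 2 it called smooth muscle lower (−0.76).

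**Figure D3:**
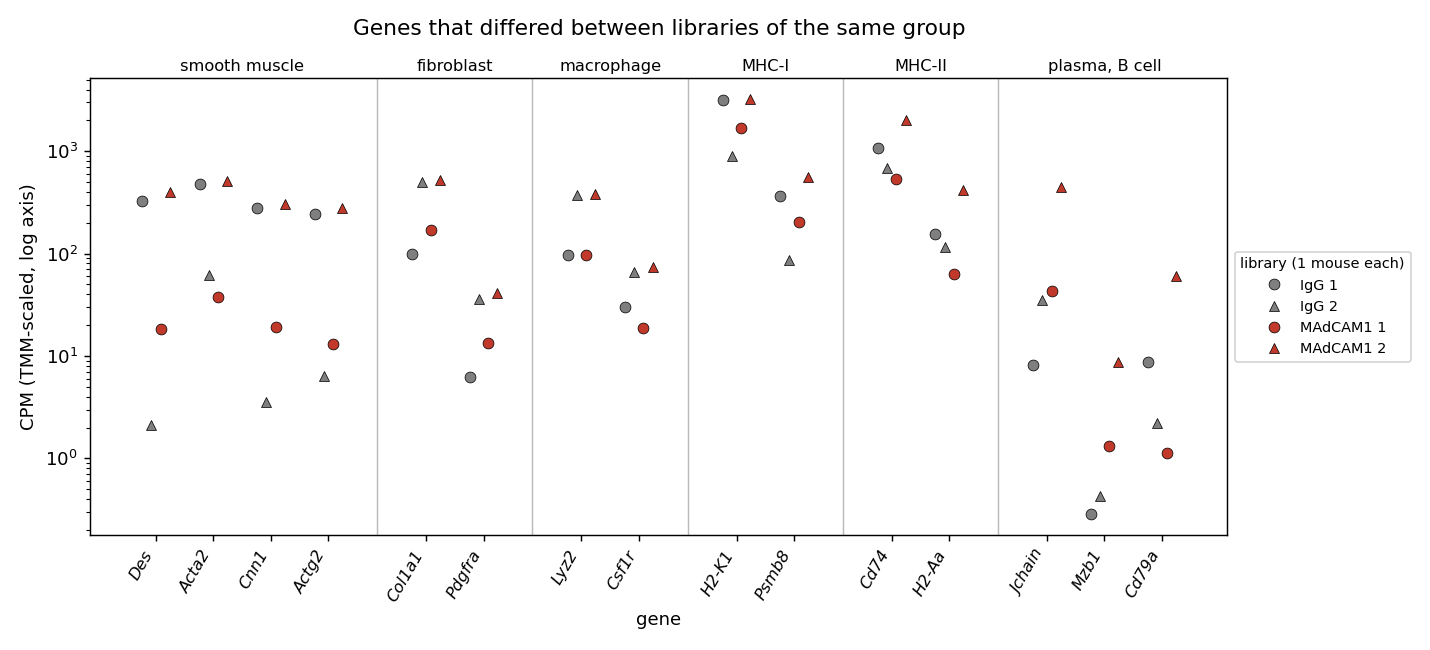
TMM-scaled CPM on a log axis for smooth muscle, fibroblast, macrophage, antigen presentation and B lineage genes in each of the 4 libraries (grey IgG, red MAdCAM1; circle mouse 1, triangle mouse 2), all chosen after their values were seen. Des ranges from 2.10 to 327 CPM within IgG and from 18.4 to 403 CPM within MAdCAM1, and Jchain is highest in MAdCAM1 2 at 449.6 CPM.

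The remaining lists were not called with all 4 libraries. Enteric neurons and glia had a median log2 fold change of 0.09 over 6 members (camera adjusted p = 0.588), with the receptor gene Ret at 6.94, 12.9, 14.5 and 9.97 CPM. Tuft cells had a median of 0.14 over 4 members (adjusted p = 0.892), with Avil at 31.4, 75.2, 33.4 and 12.8 CPM. Squamous epithelium had a median of 0.02 over 7 members (adjusted p = 0.892), with Krt15 at 71.0, 11.8, 6.93 and 17.9 CPM. The invasion and mesenchymal transition list had a median of −0.16 with 3 of 18 members lower in both and 0 higher in both (adjusted p = 0.547), and Vim, the mesenchymal intermediate filament, stood at 212 and 309 against 151 and 186 CPM. Immediate-early genes had a median of −0.16 over 14 members (adjusted p = 0.563), with Junb lower in both at 132 and 85.8 against 80.5 and 64.9 CPM and Klf6 higher in both. Heat shock and the unfolded protein response had a median of −0.23 over 12 members (adjusted p = 0.547), with the chaperone Hspa8 lower in both at 1211 and 1513 against 1024 and 1108 CPM. Mitochondrially encoded transcripts had a median of 0.20 over 13 members (adjusted p = 0.588). Adipocytes and erythroid cells were not tested as lists with all 4 libraries. Erythroid cells had 3 members among all genes and 2 tested, so the list could reach the limit of 3 in other settings. Any call of it there is not listed here. Pparg, the only adipocyte member tested, had a log2 fold change of 0.68 and an unadjusted p of 0.0314 by edgeR's quasi-likelihood test, which stays the same when adjusted over the list alone. The β-globin gene Hbb-bs stood at 9.05, 194, 26.3 and 32.6 CPM. Leaving out 1 library gave calls for neurons (2.14 without IgG 1, −0.56 without IgG 2), invasion (−0.56 without IgG 1, 0.77 without IgG 2, −0.70 without MAdCAM1 2), squamous epithelium (−0.68 without IgG 2), immediate-early genes (−0.41 without IgG 2) and mitochondrial transcripts (0.53 without IgG 2, 0.53 without MAdCAM1 2).

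Among the 36 tested lists, camera called 6 higher and 1 lower with the preset correlation. With an estimated correlation it called 0, at an adjusted p of 0.971 for every list and with 0 lists at an unadjusted p under 0.05. The estimates, from 4 libraries, were 0.494 for colonocytes, 0.952 for goblet cells, 0.173 for enteroendocrine cells and 0.596 for general epithelium. They were 0.198 for defence, 0.629 for Wnt targets and 0.0167 for hypoxia. All lie above the preset of 0.01, which treats the genes of a list as nearly independent. In simulated data, whose genes were drawn independently, camera with an estimated correlation also missed a list planted at 2-fold (adjusted p = 0.547). Camera with the preset correlation called it (3.5e-12) along with 1 of 36 unchanged lists. Genes that move together were not simulated, so this cannot show how the preset correlation fares with them. fry, which tests whether the genes of a list move 1 way on balance, also called 0, with a smallest adjusted p of 0.496 and 3 lists at an unadjusted p under 0.05. The other ways of parting the 4 libraries into 2 pairs gave 23 and 12 list calls with the preset correlation. Over all genes the quasi-likelihood test called 0 list members, and beyond the counts given above it called 0 when adjusted over the list alone. The median and mean log2 fold change and camera's direction differed in sign for some uncalled lists. Camera's direction was lower but the median and mean were positive for T cells (0.16 and 0.03), the follicle list (0.36 and 0.56), dendritic cells (0.03 and 0.08) and endothelium (0.25 and 0.10). It was lower for NK cells (median −0.14, mean 0.25), chemokines (0.14 and −0.02), smooth muscle (−0.05 and 0.01) and tuft cells (0.14 and −0.00). It was higher for monocytes (−0.02 and 0.03), the STAT3 list (−0.06 and 0.40) and squamous epithelium (0.02 and −0.20).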

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

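Counting identical genes once and the smooth muscle covariate were chosen after the data were seen, and the other alternatives before. The count of genes was 0 in each direction by edgeR's quasi-likelihood test under every scaling, filter, covariate and left-out library, and by limma-voom (unadjusted 758 higher and 259 lower). DESeq2 called 219 higher and 20 lower, and the exact test 148 higher and 9 lower. Of 168 named genes 0 reversed as called values, and 81 values newly passed, all by those 2 tools. The cause was not tested.

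Of the 7 called lists, all kept their call under RLE, library size, upper quartile, both filter alternatives, the replicate block, removal of segments, identical genes counted once and the covariate. With an estimated correlation and with fry 0 lists were called in either direction, at unchanged medians (colonocytes 1.77, goblet cells 1.88, enteroendocrine cells 2.35, epithelium 0.73, defence 1.08, hypoxia 0.45, Wnt targets −0.58), since these settings change the test alone. Adjusted p over the alternatives ran from 2.9e-17 to 0.971 for colonocytes and from 2.7e-08 to 0.9999 for Wnt targets. Lists called lower numbered 2 with no filter and 2 with the block, against 1. Newly called were plasma cells (2.30) and interferon-stimulated genes (0.40) under library size, neutrophils with no filter (−0.39), plasma cells (1.57) and neutrophils (−0.28) with the block, and interferon-stimulated genes (0.37) and MHC class I (0.35) with the covariate. The cause was not tested. The covariate was not run for the smooth muscle list itself. The block pairs mice by replicate number, and whether they share anything else is not known. Their deviations correlated at −0.135.

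Leaving out 1 library, with the lone remaining library assumed to vary like the other group, gave 1 to 16 lists lower and 8 to 19 higher (main 1 and 6). The highest counts were 19 higher without MAdCAM1 1 and 16 lower without MAdCAM1 2. Medians ranged from −0.85 to 0.59 for T cells, −0.61 to 0.67 for regulatory T cells, −1.63 to 0.43 for NK cells, −2.29 to 2.53 for B cells, 0.21 to 2.89 for plasma cells, −0.22 to 1.14 for the follicle list, −1.30 to 0.64 for monocytes, −1.11 to 0.53 for dendritic cells and −0.87 to 0.28 for neutrophils. They ranged from −0.59 to 1.14 for gut homing, −0.67 to 0.42 for chemokines, −0.40 to 1.07 for interferon-stimulated genes, −0.73 to 1.20 for MHC class II, −0.24 to 1.34 for MHC class I, −1.01 to −0.18 for Wnt targets and 0.028 to 0.26 for cell cycle. For fibroblasts they ran from −1.05 to 0.99, for endothelium −1.17 to 0.91, smooth muscle −2.90 to 3.11, neurons −0.56 to 2.14, invasion −0.70 to 0.77, squamous epithelium −0.78 to 1.38, immediate-early genes −0.41 to 0.052 and mitochondrial transcripts −0.19 to 0.53. In these fits camera called 14 lists in the direction opposite to its own with all 4 libraries, which is not always the sign of the median: regulatory T cells −0.61, B cells −2.29, monocytes −1.30, gut homing −0.59, interferon-stimulated genes −0.40, MHC class II −0.73 and fibroblasts −1.05 without MAdCAM1 2, the follicle list 1.14, dendritic cells 0.42, endothelium 0.91 and smooth muscle 0.84 without MAdCAM1 1, and neurons −0.56, invasion 0.77 and squamous epithelium −0.68 without IgG 2. Over all 18 alternatives 142 uncalled results changed direction. The cause was not tested. Depth limits genes of a few tags such as Itga4, with 2 tags in MAdCAM1 1.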

Other observations

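The gene families, the splits of the libraries, the cell cycle test and both tests on MAdCAM1 2 were chosen after the results were seen, and the Hox test before. Genes of drug and lipid metabolism (cytochrome P450, carboxylesterase, sulfotransferase, UDP-glucuronosyltransferase, glutathione transferase and aldo-keto reductase) were higher in both MAdCAM1 libraries in 36 of 67 cases, or 53.7% against 19.3% of other genes, where chance gives 16.7%, and 1 was lower in both. Cyp4f40, for example, stood at 8.08 and 6.25 CPM in IgG and 25.2 and 33.0 CPM in MAdCAM1. Brush border genes were higher in both in 8 of 15 cases (2 lower) and solute carriers in 76 of 215 (21 lower). By Fisher's exact test, two-sided and adjusted over the 3 families tried, p was 1.3e-09, 0.00358 and 6.8e-08, though genes are not independent. Named genes and list members were left out. Scaled by library size alone the counts were 31, 8 and 59 higher and 4, 2 and 39 lower, where the shares over all genes were 13.6% higher and 28.6% lower, against 19.7% and 18.7% with TMM. In the other ways of pairing the libraries, metabolic genes on either side numbered 3 and 7, and 9 and 11, brush border genes 0 and 2, and 1 and 2, and solute carriers 22 and 24, and 46 and 26, so solute carriers were uneven in another pairing too.

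For the higher epithelial lists and lower Wnt targets, the 4 libraries can be parted into pairs in 3 ways, too few for a share under 0.05, and all 3 gave at least the 7 list calls of the real grouping, with 23 in the highest other. The real grouping had the most genes at an unadjusted p under 0.05 (991) and by the exact test (157). The others had 385 and 61, and 908 and 116. Genes without overlap did not single it out. They made up 19.7% and 18.7% on the sides of the real grouping. Pairing IgG 1 with MAdCAM1 2 gave 21.4% and 17.7%, and the remaining pairing gave less on both sides. The real grouping alone called the enteroendocrine, defence and hypoxia lists. Another grouping also called colonocytes, goblet cells and general epithelium, and the remaining one Wnt targets. A different tumour position along the colon may be involved. Of the 6 tested posterior Hox genes, 33.3% lay on one side (Hoxa10 and Hoxa13, higher), which meets neither bound set for that test. That share does not show that IgG 2 was the lowest library for each of them but Hoxb13. Hoxd13 stood at 76.5, 6.43, 36.9 and 69.2 CPM in the order IgG 1, IgG 2, MAdCAM1 1, MAdCAM1 2. Hoxd11 stood at 14.2, 1.42, 10.6 and 9.91 CPM, and Hoxb13 at 107, 173, 186 and 130 CPM. IgG 2 also had the lowest median level of the colonocyte, goblet and enteroendocrine lists. More non-tumour mucosa is a further candidate, which the cell cycle median of 0.13, within its spread of 0.209, leaves open. The antibody, the difference the design names, stays among the open explanations.

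For the plasma cell genes in MAdCAM1 2, a lymphoid follicle in that tissue is a candidate source, as a hypothesis from values already seen. The B cell and follicle members had a median log2 ratio of 1.09 (SE 0.36) to the highest other library. The B cell list carried it more (1.62, SE 0.41, 5 of 5 highest there) than the follicle list (0.91, SE 0.69, 4 of 7). The plasma cell list itself stood higher than both (2.63, SE 0.50, 6 of 7), and MHC class II stood at 0.90 (SE 0.12, 8 of 8). Each SE and spread here is over the genes of a list in 1 library. It does not measure the spread between mice, and the genes are not independent. More immune cells of every kind would raise T cell, macrophage and neutrophil genes as well, and the median ratio of these together was −0.13 (SE 0.17). Apart, it was 0.49 (SE 0.56) for T cells, 0.08 (SE 0.095) for monocytes and −0.92 (SE 0.60, 2 of 16 highest there) for neutrophils, so the lists differ, but the members together lay within their spread of 0 and this stays open. No biological explanation from the design was tested, since both mice of the group received the same antibody.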
